A study of Mus musculus with 12 samples.

How the data were processed

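Gene expression was measured in mouse macrophages grown from bone marrow, with 1 Affymetrix array per sample and 12 arrays in all. The cells came from 2 genotypes on the strain that the labels give as 129-SvEv-Tac. IL10-/- cells lack the gene for interleukin 10 (IL-10), a cytokine that restrains macrophage activation. p50-/-IL10-/- cells also lack Nfkb1, which codes for the p50 and p105 subunits of the transcription factor NF-kB. Below, p50 loss and without p50 stand for the loss of both, whose effects these genotypes cannot tell apart. Marrow cells were grown for 5 days with 30% L-cell conditioned medium, a source of macrophage growth factor, and 10% serum, per the labels. Cells of each genotype were left unstimulated, given 1 ng/ml lipopolysaccharide (LPS, a component of bacterial cell walls), or given 1 ng/ml LPS with 0.3 ng/ml IL-10. RNA was taken at 4 h after stimulation, and 6 µg of total RNA was labelled for each array. Each of the 6 groups held 2 arrays, which the labels call biological replicates, so the p-values measure the spread between these samples. Whether arrays that carry the same replicate number in different groups came from 1 culture is not given in the sources used here.

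The authors deposited 1 table of log2 expression values for 22690 probe sets, made with RMA per the labels, which also name limma without a role. Versions and options of both were not given. RMA corrects for background, gives the arrays a common distribution and summarises the probes of each probe set. The array medians lay between 6.92 and 6.96, so a change in total RNA between groups is not visible in these values. RMA values compress changes of dim genes, and probe sets whose names mark shared probes can take signal from related genes. Arrays give no count of molecules, and their number limits the precision.

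The 64 control probe sets were left out. Of the rest, 20380 carried 1 gene symbol in the probe table, 691 carried several and 1555 carried no gene. Gene identifiers of 20351 probe sets matched the mouse gene table, and 0 symbols changed by that match. Each gene was represented by its probe set with the highest mean over the 12 arrays, which gave 12393 genes, of which 4956 had more than 1 probe set. Transcripts of Nfkb1 itself were not analysed here, and the genotypes were taken from the labels. The position of the Il10 probes relative to the deleted part of the gene is not given in the sources used here. The genome build behind the probe annotation is not given either, so the gene table served for names and for neighbours of Nfkb1 only, and no coordinates are printed.

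Groups were compared with limma 3.58.1 in R 4.3.3. A mean was fitted per group, with 6 residual degrees of freedom and a prior worth 4.47 degrees of freedom from all genes. Across 12 contrasts, a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes of a contrast, two-sided). The contrasts were LPS against no stimulus, LPS with IL-10 against LPS alone, and LPS with IL-10 against no stimulus, each in both genotypes. The others were the genotype difference at each stimulus, its average over the 3 stimuli, and the genotype differences of the LPS response and of the IL-10 effect. The test borrows spread across genes, because an exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. The median standard error (SE) of a difference between a pair of groups was 0.0998 log2. Log2 differences are given with their SE, with n = 2 arrays in each group. Folds are 2 to the power of the fitted difference.

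Gene groups were 20 lists with 438 entries, of which 377 were measured. They covered inflammatory cytokines and chemokines, NF-kB pathway and feedback genes, interferon-stimulated genes, IL-10 and STAT3 response genes, antimicrobial and lipid mediator enzymes, and MAP kinase phosphatases with mRNA decay factors. Others covered MHC class II presentation, co-stimulation and adhesion, cholesterol synthesis, glycolysis and hypoxia, cell cycle, macrophage identity, and heat shock with immediate early genes. The last 7 lists held markers of other cell types, namely neutrophils, dendritic cells, B cells, T and NK cells, erythroid cells, mast cells with basophils, and stromal cells. For each list the members called higher or lower were counted, over all genes and with p-values adjusted over the list alone. Lists were also tested with limma's camera, which asks whether a list's genes shift relative to all other genes. Camera ran with a preset correlation between genes of 0.01 and with a correlation estimated from the arrays, each adjusted over the 20 lists of a contrast. The mean of a list on each array was compared between the genotypes with an exact permutation test within stimuli, two-sided, over 216 assignments, whose smallest possible p is 0.00926 if the arrays are independent.

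Genes were named by rule. In each contrast these were the 10 largest increases and 10 largest decreases among called genes whose arrays did not overlap between the groups, or 5 and 5 in the LPS with IL-10 against no stimulus, averaged and interaction contrasts, where the last 3 needed only the adjusted p. The rule added the 2 largest called increases and decreases of each list described, and Nfkb1 and Il10 always, although Nfkb1 was not analysed here. Predicted genes without a proper symbol could be passed over. Of 585 called values of named genes, 228 belonged to genes with other probe sets. In 60 of these no other probe set was called the same way, and in 0 was another called in the opposite direction. The lists, the contrasts, the naming rule and the first set of alternatives were fixed before the data were examined.

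The alternatives were a trended and robust prior, a filter to genes with at least 6 log2 on at least 2 arrays, the mean of a gene's probe sets, all 22626 probe sets as units, quantile normalization applied again, centring of each array on its median, a replicate block over all groups or within genotypes (consensus correlation 0.034 for the random block), fits on only the groups compared, and leaving out each array in turn. A further pair was chosen after seeing the data, namely camera with the block within genotypes, and leaving out together the 3 IL10-/- arrays numbered 2. The fit was tested on simulated data with 200 seeded genes among 12393. For a genotype difference in LPS-treated cells, 66% of seeded log2 differences of 0.5, 97% of those of 1 and 100% of those of 2 were recovered, with 8 false calls. For the genotype difference of the LPS response the shares were 24%, 94% and 100%, with 9 false calls.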

Results

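Expression of 12393 genes was measured on 12 arrays of mouse bone marrow macrophages, with 2 genotypes (IL10-/- and p50-/-IL10-/-), 3 stimuli (none, LPS, LPS with IL-10) and 2 arrays in each of the 6 groups. Both genotypes carry a knockout of Il10 per the labels, which was not checked on the arrays, and IL-10 was added at 0.3 ng/ml. The series title states its subject as the control of LPS-induced genes by the p50 and p105 subunits and by IL-10. Arrays of a group correlated at 0.992 to 0.997 over all genes. The first principal component of all arrays carried 59.0% of the variance and the next one 18.8%. Array minima were 3.21 to 3.29 log2, and the number of arrays limits the precision. Lower quartiles of the arrays lay at 5.49 to 5.60 log2, and where a group mean under 5.60 enters a change its size and rank are uncertain. The genes given for which this holds include Ankrd33b, BC023105, Ccn2, Ch25h, Cnr2, Eno2, Gbp2b, Gem, Gpr34, Gpr35, Il12b, Il6, Mcoln3, Ptgs2, Qpct, Serpinb2 and Zbtb46, in changes that involve such a mean.

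Among the targeted genes, Il10 (gene ID 16153) was measured by a single probe set, and Nfkb1 was not analysed here, so the loss of p50 in every comparison below rests on the labels. In unstimulated IL10-/- cells Il10 read 6.78 ± 0.29 log2 (mean ± SD, n = 2 arrays), with LPS 7.63 ± 0.11, and with LPS and IL-10 6.89 ± 0.10. In p50-/-IL10-/- cells the levels were 6.74 ± 0.28 unstimulated, 8.99 ± 0.18 with LPS, and 8.01 ± 0.04 with LPS and IL-10. The location of this probe set relative to the deletion is unknown, so its signal checks nothing about the knockout. The signal rose with LPS by 0.86 ± 0.16 log2 in IL10-/- cells and by 2.25 ± 0.16 in p50-/-IL10-/- cells (SE, n = 2 arrays per group). The response was larger by 1.39 ± 0.22 without p50 (adjusted p 0.017), a call that ended in 4 of 8 fits with 1 array left out (highest adjusted p 0.0878, without array 1 of LPS-treated p50-/-IL10-/- cells). Without p50 it was higher by 1.35 ± 0.16 with LPS and by 1.11 ± 0.16 with LPS and IL-10, and it did not differ detectably without stimulus (-0.04 ± 0.16).

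LPS treatment of IL10-/- cells asked which genes macrophages with the Il10 knockout induce. The chemokine gene Cxcl10 (gene ID 15945) rose 49.1-fold, by 5.62 ± 0.36 log2 (n = 2 arrays per group). Il12b (gene ID 16160), a subunit of interleukin 12, rose by 5.21 ± 0.21, and the cytokine gene Il6 (gene ID 16193) by 4.50 ± 0.33. Both were dim in unstimulated cells (4.76 and 3.87 log2), so the sizes of these increases are uncertain. Ch25h, which makes an antiviral oxysterol, rose by 4.92 ± 0.38, the co-stimulatory receptor Cd40 by 4.65 ± 0.16 and the neutrophil attractant Cxcl1 by 4.53 ± 0.26. The largest measured falls were in Cytip, a regulator of adhesion (-2.96 ± 0.20), in the cannabinoid receptor Cnr2 (-2.91 ± 0.20), in the vesicle transport gene Rab11fip5 (-2.61 ± 0.18) and in the microglial and macrophage receptor Gpr34 (-2.59 ± 0.15, to a dim 4.25). The myeloid transcription factor Cebpa changed by -2.39 ± 0.18, and the receptor for apoptotic cells Mertk by -1.74 ± 0.19. Of 27 inflammatory cytokine and chemokine genes, 17 rose and 10 were not called (21 higher when adjusted over the list alone, adjusted camera p 0.00832 with the estimated correlation). Of 21 NF-kB pathway genes, 18 rose, among them Traf1 (3.71 ± 0.12) and Nfkbiz (2.57 ± 0.22), with an estimated-correlation p of 0.00083. Of 48 interferon-stimulated genes, 39 rose, 1 fell (Irf8) and 8 were not called (43 higher and 1 lower adjusted over the list alone), and the list's camera p was 5.14e-23 with the preset and 0.302 with the estimated correlation. Antimicrobial and lipid mediator enzymes rose in 19 of 26 cases, such as Acod1 (3.54 ± 0.27), with an estimated-correlation p of 0.00347, and co-stimulation and adhesion genes in 11 of 17 (estimated-correlation p 0.00347). Cholesterol synthesis genes rose in 10 of 19 cases, such as Idi1 (1.40 ± 0.22), and fell in 2 (estimated-correlation p 0.387). Cell cycle genes fell in 9 of 31 cases, such as Mcm7 (-1.58 ± 0.14), whose probe set name marks shared probes, while Mki67 alone rose (1.87 ± 0.26), and the list had a camera p of 0.00465 with the preset and 0.387 with the estimated correlation. In all, 3078 genes were called, 962 higher and 2116 lower, of which 328 and 242 changed at least 2-fold. Without array 2 of the unstimulated cells the count was 1950.

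The same treatment in p50-/-IL10-/- cells asked which of these responses occur without p50 and p105. Il12b rose by 6.87 ± 0.21 log2 (n = 2 arrays per group) and Il6 by 6.06 ± 0.33, from dim levels of 5.20 and 3.88. Ch25h and Cxcl10 each rose by 5.69 (± 0.38 and ± 0.36), and the T cell attractant Cxcl9 by 5.64 ± 0.44. Cebpa fell by 3.72 ± 0.18, the chemokine receptor Cxcr4 by 3.28 ± 0.19 and the early response factor Fos by 3.00 ± 0.23. Of 27 inflammatory genes, 18 rose and 9 were not called (18 adjusted over the list alone, estimated-correlation p 0.0113). Of 21 NF-kB pathway genes, 18 rose, led by the inhibitor Nfkbie (3.52 ± 0.13), and 1 fell (estimated-correlation p 0.00124). Interferon-stimulated genes rose in 36 of 48 cases, with 12 not called (39 adjusted over the list alone, estimated-correlation p 0.353). Among phosphatases and mRNA decay factors, Dusp2 rose by 3.45 ± 0.16, whereas Zfp36l2 fell by 2.24 ± 0.13, and the list of 10 held 5 increases and 4 decreases, with a positive median (0.183) and a negative mean (-0.143). Glycolysis and hypoxia genes split into 6 higher, such as the hexokinase Hk2 (1.26 ± 0.10), and 10 lower, such as Vegfa (-1.65 ± 0.15). Called genes numbered 4012, with 1273 higher and 2739 lower, and 451 and 366 of them changed at least 2-fold.

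Most LPS responses were shared by the genotypes. Of 962 genes raised in IL10-/- cells, 746 were also raised in p50-/-IL10-/- cells (98.8 if independent), and 1802 of 2116 lowered genes were also lowered (468 if independent). Log2 changes in the genotypes correlated at 0.888 across genes, which are not independent replicates. A direct test of the difference called 147 genes, 91 with a higher and 56 with a lower change without p50, but the excess of higher changes ended in 4 of 8 fits with 1 array left out (16 and 16, 20 and 23, 120 and 135, and 19 and 20). The Mediator subunit gene Med21 rose in both genotypes, from 7.22 to 7.85 log2 in IL10-/- and from 7.48 to 10.46 in p50-/-IL10-/- cells, a difference of 2.35 ± 0.23 (adjusted p 0.00164). The transcription factor Nfil3 changed from 7.66 to 7.27 and from 7.16 to 8.65, a difference of 1.87 ± 0.20. The scavenger receptor Marco went from 7.05 to 10.27 in IL10-/- cells and from 7.56 to 7.50 without p50 (-3.28 ± 0.44). The phosphatase Dusp1 stood at 10.10 and 9.97 in IL10-/- cells and fell from 10.04 to 8.14 without p50 (-1.77 ± 0.17). The enolase Eno2 (-2.65 ± 0.25) and the receptor Clec4e (-0.91 ± 0.12) also had lower changes, and Nfkbie (1.37 ± 0.18) and Hk2 (1.08 ± 0.14) higher ones. These genes remained called with each of the 8 arrays left out in turn. The response of Il12b was larger by 1.66 ± 0.30 (adjusted p 0.0323) and that of the interferon gene Ifnb1 by 1.48 ± 0.26, but these calls ended in 5 and 6 of 8 such fits (highest adjusted p 0.138, without array 1 of LPS-treated p50-/-IL10-/- cells, and 0.117, without array 1 of unstimulated p50-/-IL10-/- cells). The count of 147 became 56, 32, 43, 255, 95 and 39 without, in turn, unstimulated IL10-/- array 2, unstimulated p50-/-IL10-/- arrays 1 and 2, LPS-treated IL10-/- arrays 1 and 2, and LPS-treated p50-/-IL10-/- array 1.

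**Figure D1:**
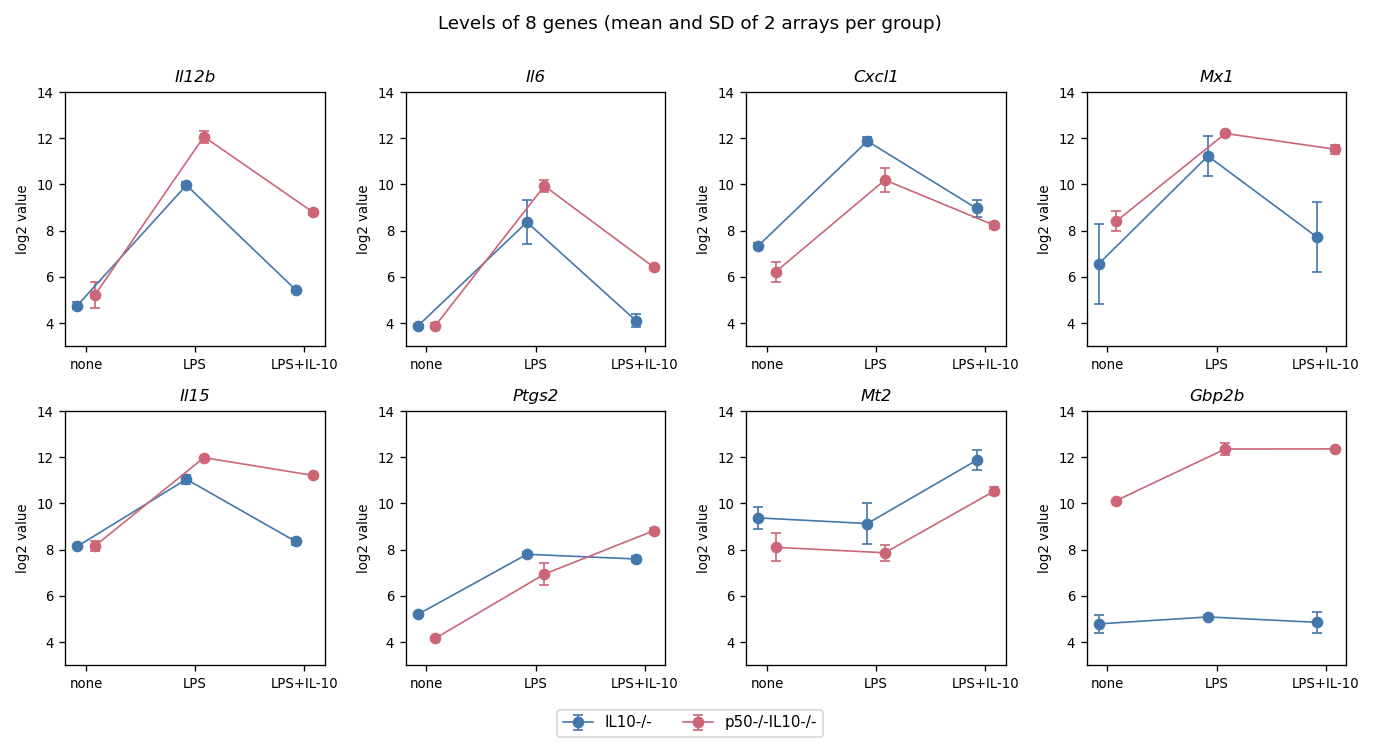
Expression of 8 genes in log2 units (vertical axis) by stimulus (horizontal axis) for both genotypes, with points at the group mean and bars at the SD of 2 arrays. Il12b with LPS and IL-10 stood at 5.45 in IL10-/- and 8.80 in p50-/-IL10-/- cells, and Gbp2b stood at 4.78 to 5.09 in IL10-/- and 10.12 to 12.36 in p50-/-IL10-/- cells.

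IL-10 added together with LPS asked how the cytokine alters the LPS response, here in IL10-/- cells. Metallothionein gene Mt2 (gene ID 17750) was 6.67-fold higher than with LPS alone (2.74 ± 0.41 log2, n = 2 arrays per group). The interleukin 4 receptor Il4ra was 5.28-fold higher (2.40 ± 0.13), the orphan receptor Gpr35 higher by 2.12 ± 0.20, the zinc transporter Slc39a14 by 2.04 ± 0.14 and the interleukin 1 antagonist Il1rn by 1.94 ± 0.16. Il12b changed by -4.52 ± 0.21 and Il6 by -4.27 ± 0.33, to dim levels (5.45 and 4.10) that leave these sizes uncertain, and Cxcl1 by -2.91 ± 0.26. The antiviral gene Mx2 changed by -2.73 ± 0.23 and the cytokine gene Il15, which sustains NK cells, by -2.69 ± 0.12. Of 27 inflammatory genes, 11 were lower and 0 higher (14 lower adjusted over the list alone, estimated-correlation p 0.0163). Of 21 NF-kB pathway genes, 10 were lower, such as Traf1 (-1.53 ± 0.12) and Rel (-1.19 ± 0.17), and 2 higher, such as Bcl3 (1.29 ± 0.15), with an estimated-correlation p of 0.0108. Of 48 interferon-stimulated genes, 20 were lower, 0 higher and 28 not called (34 lower and 1 higher adjusted over the list alone), with a median of -1.39 and a camera p of 7.78e-26 with the preset and 0.219 with the estimated correlation. Without the IL10-/- arrays numbered 2, which read lower for this list, the median was -1.36. IL-10 and STAT3 response genes were higher in 12 of 22 cases and lower in 2 (estimated-correlation p 0.00901). Glycolysis and hypoxia genes were higher in 13 of 21 cases and lower in 0, such as the regulatory enzyme Pfkfb3 (2.83-fold) and Egln3 (1.14 ± 0.15), with an estimated-correlation p of 0.0123 and 16 higher adjusted over the list alone. In all, 415 genes were higher and 350 lower, 765 together, a balance that turned without LPS array 1 (222 and 244) and in the fit on only the groups compared (139 and 144). The total was 466 without LPS array 1, and 429 and 426 without LPS and IL-10 arrays 1 and 2. Il10 itself was lower by a log2 difference of -0.74 ± 0.16, a call that ended in 3 of 4 such fits (highest adjusted p 0.125, without LPS array 1).

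In p50-/-IL10-/- cells IL-10 raised Mt2 6.36-fold (2.67 ± 0.41 log2, n = 2 arrays per group), the ribosome assembly gene Tma16 by 2.45 ± 0.19, Slc39a14 by 2.40 ± 0.14, Il4ra by 2.36 ± 0.13 and the transcriptional inhibitor Id1 by 2.21 ± 0.25. Cyclooxygenase gene Ptgs2 (gene ID 19225) rose 3.67-fold (1.88 ± 0.18). Il6 fell by 3.51 ± 0.33, Il12b by 3.27 ± 0.21 and Cxcl1 by 1.96 ± 0.26. Of 27 inflammatory genes, 7 were lower and 1 higher (10 and 3 adjusted over the list alone), with a camera p of 0.000114 with the preset and 0.207 with the estimated correlation. Of 48 interferon-stimulated genes, 3 were lower and 45 not called (5 lower adjusted over the list alone), with a median of -0.30 and a camera p of 7.65e-07 with the preset and 0.632 with the estimated correlation. The SE of a gene came from all 6 groups, including the IL10-/- arrays, which differed more between replicates for this list. In p50-/-IL10-/- cells the list mean read 11.84 and 11.64 with LPS, and 11.18 and 11.39 with LPS and IL-10, without overlap. The 45 genes not called therefore do not show that IL-10 left them unchanged. IL-10 and STAT3 response genes were higher in 10 of 22 cases, such as Ier3 (1.94 ± 0.15), and lower in 1 (estimated-correlation p 0.0154). NF-kB pathway genes were higher in 3 of 21 cases, such as Bcl3 (1.88 ± 0.15), and lower in 5, such as Rel (-1.26 ± 0.17). Glycolysis and hypoxia genes were higher in 3 of 21 cases (8 adjusted over the list alone), with a preset p of 0.00642 and an estimated-correlation p of 0.315. In all, 814 genes were called, 458 higher and 356 lower. After each array was centred on its median these were 309 and 396, so the balance of directions depends on the scaling, which the median change of all genes (0.05 log2) reflects. It also turned without LPS array 2 (216 higher and 263 lower), without LPS and IL-10 array 2 (133 and 139) and in the fit on only the groups compared (303 and 310). The total was 270 and 479 without LPS arrays 1 and 2, and 327 and 272 without LPS and IL-10 arrays 1 and 2. The call of Il10 (-0.98 ± 0.16) ended without LPS array 1 (adjusted p 0.0597).

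Of the 328 genes that LPS raised at least 2-fold in IL10-/- cells, IL-10 lowered 145 (44.2%) and raised 17 there, with a median of -0.62 log2. Of the 451 such genes of p50-/-IL10-/- cells, IL-10 lowered 111 (24.6%) and raised 10 there, with a median of -0.33. These comparisons share the LPS arrays, and in 20 simulated data sets without an IL-10 effect this sharing moved the median to -0.0142 in IL10-/- and -0.0152 in p50-/-IL10-/- cells. The simulated noise was independent between genes, so a shift shared by many genes of an LPS array was not covered. With the genes taken from the other genotype, which shares no arrays, IL-10 lowered 196 of 451 (43.5%) in IL10-/- cells and 44 of 328 (13.4%) in p50-/-IL10-/- cells. The genotypes shared 189 raised genes (15.3 if independent) and 143 lowered genes (10.1 if independent), and the changes correlated at 0.604 across genes. Tested directly, the IL-10 effect differed between genotypes for 17 genes, 12 higher and 5 lower without p50, and for 74 (53 and 21) with a replicate block within genotypes, so the number depends on whether array numbers mark cultures. The excess of higher differences ended in 3 of 8 fits with 1 array left out, with 6 higher and 8 lower without LPS-treated p50-/-IL10-/- array 2, and 2 and 2, and 2 and 3, without arrays 1 and 2 of p50-/-IL10-/- cells given both. Il15 went from 11.05 log2 with LPS to 8.36 with LPS and IL-10 in IL10-/- cells and from 11.98 to 11.21 without p50, a difference of 1.92 ± 0.17 (adjusted p 0.00295). The interferon regulatory factor Irf1 went from 12.54 to 11.22 and from 12.98 to 12.71 (1.06 ± 0.10). Serpinb2, an inhibitor of plasminogen activators, went from 5.39 to 6.75 and from 4.52 to 4.67 (-1.20 ± 0.11), where all but the 6.75 are dim and the size is uncertain. These calls were kept with each of 8 arrays left out. Ptgs2 went from 7.80 to 7.60 and from 6.94 to 8.82 (2.08 ± 0.26, adjusted p 0.0115). Its other probe set was not called for this difference, and the call ended in 4 of the 8 fits (highest adjusted p 0.0845, without array 1 of p50-/-IL10-/- cells given LPS and IL-10). The count of 17 became 10 and 43 without LPS-treated IL10-/- arrays 1 and 2, 11 without LPS-treated p50-/-IL10-/- array 1, 11 without array 2 of IL10-/- cells given LPS and IL-10, and 4 and 5 without arrays 1 and 2 of p50-/-IL10-/- cells given both.

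**Figure D2:**
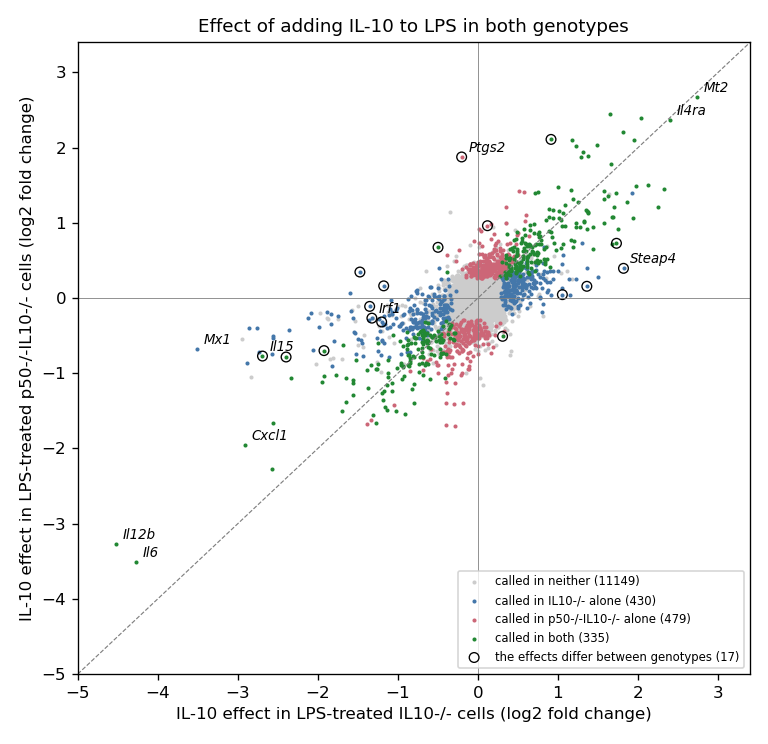
Log2 change with IL-10 in LPS-treated cells for 12393 genes, IL10-/- cells on the horizontal and p50-/-IL10-/- cells on the vertical axis, with each point a gene. Of these, 335 were called in both genotypes, 430 in IL10-/- cells alone, 479 in p50-/-IL10-/- cells alone and 11149 in neither, and rings mark the 17 whose effect differed between genotypes.

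Cells given LPS and IL-10 were also compared with unstimulated cells, to show which LPS responses remain in the presence of IL-10. In IL10-/- cells the cytokine signalling inhibitor Socs3 rose by 4.28 ± 0.08 log2 (n = 2 arrays per group), the formyl peptide receptor Fpr2 by 4.08 ± 0.32, Cd40 by 3.99 ± 0.16 and Il1rn by 3.43 ± 0.16, and the lipid phosphatase Lpin1 fell by 3.32 ± 0.25. In p50-/-IL10-/- cells Socs3 rose by 5.25 ± 0.08, Cxcl10 by 5.15 ± 0.36, Cd40 by 5.00 ± 0.16 and Ptgs2, dim in unstimulated cells (4.16), by 4.66 ± 0.18, and Enc1 fell by 3.64 ± 0.09. Interferon-stimulated genes were higher in 11 of 48 cases in IL10-/- cells (12 adjusted over the list alone, estimated-correlation p 0.472). Without the low-reading arrays numbered 2 their median change there was 0.77. In p50-/-IL10-/- cells 32 of 48 were higher (36 adjusted over the list alone, estimated-correlation p 0.506). Inflammatory genes were higher in 14 and 18 of 27 cases (14 and 21 adjusted over the list alone), with estimated-correlation p-values of 0.0216 and 0.0186. Glycolysis and hypoxia genes were higher in 14 of 21 cases in IL10-/- cells, such as Slc2a1 (2.00 ± 0.12), and in 9 of 21 in p50-/-IL10-/- cells (estimated-correlation p 0.0184 and 0.589). Called genes numbered 2411 in IL10-/- cells (860 higher, 1551 lower) and 4703 in p50-/-IL10-/- cells (2070 higher, 2633 lower). The first count became 1469 without unstimulated array 2 and 1482 without LPS and IL-10 array 1, and the second became 3035 and 2909 without arrays 2 of the unstimulated and of the doubly treated cells. The 2070 higher calls became 1713 with the filter on dim genes (898 in IL10-/- cells). They became 1809 after quantile normalization again and 2190 after centring. In p50-/-IL10-/- cells the median change was 0.046 over all genes and -0.034 over the genes the filter kept. The number of higher calls there thus depends in part on dim genes and scaling.

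The comparison of the genotypes in unstimulated cells asked which genes differ with the loss of p50 and p105 before any LPS. The interferon-inducible GTPase gene Gbp2b (gene ID 14468) was higher in p50-/-IL10-/- cells by 5.34 ± 0.21 log2 (n = 2 arrays per group), over a dim level in IL10-/- cells (4.78 to 5.09 across the stimuli) that leaves the size uncertain. The phosphodiesterase Gdpd3 was higher by 4.22 ± 0.34, the Golgi gene Tmem87a by 2.77 ± 0.11, the glutaminyl cyclase Qpct by 2.60 ± 0.20 and the integrin Itgax (CD11c) by 2.54 ± 0.35. The matrix genes Thbs1 (-3.77 ± 0.22) and Ccn2 (-2.90 ± 0.21), Ankrd33b (-2.65 ± 0.14) and the bacterial lipoprotein receptor Tlr1 (-2.43 ± 0.28) were lower. The co-stimulatory genes Cd86 (-1.23 ± 0.17) and Cd83 (-1.03 ± 0.15), the cytokine subunit Ebi3 (-1.45 ± 0.14) and Nfkbie (-1.09 ± 0.13) were lower too. Markers of neutrophils and their precursors were lower in 7 of 12 cases, such as S100a9 (-1.22 ± 0.08) and Chil3 (-1.18 ± 0.10), with 9 lower adjusted over the list alone and an estimated-correlation p of 0.00569. Stromal markers were lower in 6 of 13 cases (8 adjusted over the list alone, estimated-correlation p 0.086). Of 48 interferon-stimulated genes, 1 (Gbp3, 1.54 ± 0.23) was called higher over all genes and 25 when adjusted over the list alone, with a median of 0.88 (estimated-correlation p 0.326). Without IL10-/- array 2, which read 7.99 for this list against 9.06 on array 1, and its partners at the other stimuli, the median was 0.38. The call of Gbp3 ended without p50-/-IL10-/- array 1 (adjusted p 0.0628). In all, 156 genes were higher and 162 lower, 318 together, and the total was 131 without IL10-/- array 2, and 151 and 101 without p50-/-IL10-/- arrays 1 and 2. Of the 46 genes picked by the naming rule and called here, 23 lost the call in at least 1 of the 4 fits with 1 array left out, and of the genes given in this comparison only Gbp3 was among them.

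With LPS, Gbp2b was higher without p50 by 7.27 ± 0.21 log2 (n = 2 arrays per group), Gdpd3 higher by 4.58 ± 0.34, Med21 by 2.61 ± 0.17 and the cytokine signalling inhibitor Socs1 by 2.27 ± 0.38. Il12b was higher by 2.10 ± 0.21 and Il1a by 1.75 ± 0.19. Ankrd33b (-3.85 ± 0.14), Fos (-2.92 ± 0.23), Marco (-2.77 ± 0.31), Tlr1 (-2.70 ± 0.28) and Cxcl1 (-1.68 ± 0.26) were lower. The phosphatases Dusp1 (-1.83 ± 0.12) and Dusp6 (-1.75 ± 0.13) were among 5 of 10 phosphatase and mRNA decay genes that were lower, with 1 higher (estimated-correlation p 0.247). The 27 inflammatory genes split into 4 higher and 4 lower (5 and 4 adjusted over the list alone), with a median of -0.002, a mean of 0.107 and a camera p of 0.697. Cholesterol synthesis genes were lower in 11 of 19 cases, such as Idi1 (-1.16 ± 0.22), and higher in 0 (16 lower adjusted over the list alone), with a camera p of 3.47e-08 with the preset and 0.247 with the estimated correlation. Glycolysis and hypoxia genes were lower in 7 of 21 cases, such as Vegfa (-1.85 ± 0.15) and Pfkl (-1.12 ± 0.08), and higher in 3, such as Hk2 (0.78 ± 0.10), with an estimated-correlation p of 0.433. Interferon-stimulated genes were higher in 8 of 48 cases and lower in 0 (17 higher adjusted over the list alone), with a median of 0.80 (estimated-correlation p 0.433), which was 0.43 without the IL10-/- arrays numbered 2. Neutrophil markers were lower in 8 of 12 cases (estimated-correlation p 0.0373) and stromal markers in 6 of 13, with 1 higher (estimated-correlation p 0.348). Called genes numbered 1535, with 702 higher and 833 lower, but the balance turned without IL10-/- array 2 (470 and 407), without p50-/-IL10-/- array 2 (573 and 480), without all IL10-/- arrays numbered 2 (526 and 414) and in the fit on only the groups compared (313 and 268). The total was 877 without IL10-/- array 2 and 671 without p50-/-IL10-/- array 1.

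With LPS and IL-10, Gbp2b was higher without p50 by 7.51 ± 0.21 log2 (n = 2 arrays per group), the interferon-induced genes Oasl1 by 3.78 ± 0.58 and Gbp6 by 3.37 ± 0.55, Il12b by 3.35 ± 0.21 and Il6 by 2.33 ± 0.33. Prostaglandin E synthase Ptges was higher by 2.03 ± 0.18 and Cd40 by 1.48 ± 0.16. Tlr1 (-3.01 ± 0.28), the mRNA decay factor Zfp36l1 (-2.46 ± 0.19), Fos (-2.43 ± 0.23) and Serpinb2 (-2.08 ± 0.08) were lower. Of 48 interferon-stimulated genes, 37 were higher, 0 lower and 11 not called (44 higher adjusted over the list alone), with a median of 2.03 (1.46 without the IL10-/- arrays numbered 2) and a camera p of 7.01e-20 with the preset and 0.246 with the estimated correlation. Mx1 was higher by 3.81 ± 0.77, but its call ended without IL10-/- array 2 (adjusted p 0.0669) and without p50-/-IL10-/- array 2 (0.0554). Inflammatory genes were higher in 9 of 27 cases and lower in 0 (11 and 1 adjusted over the list alone, estimated-correlation p 0.196). Glycolysis and hypoxia genes were lower in 13 of 21 cases, such as Vegfa (-1.52 ± 0.15) and Bnip3 (-1.44 ± 0.12), and higher in 2 (15 and 3 adjusted over the list alone), with a preset p of 3.01e-08 and an estimated-correlation p of 0.0839. Cholesterol synthesis genes were lower in 12 of 19 cases, such as Sqle (-1.13 ± 0.15), and higher in 0 (17 lower adjusted over the list alone, estimated-correlation p 0.183). Neutrophil markers were lower in 6 of 12 cases (estimated-correlation p 0.0748) and stromal markers in 6 of 13 (estimated-correlation p 0.271). In all, 2231 genes were called, 940 higher and 1291 lower. The total was 987 without IL10-/- array 2, and 1136 and 1010 without p50-/-IL10-/- arrays 1 and 2.

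Averaged over the 3 stimuli, p50 loss changed 3182 genes, 1313 higher and 1869 lower, with 109 and 65 of them at least 2-fold. Gbp2b was higher by 6.71 ± 0.12 log2 (n = 6 arrays per genotype), Gdpd3 higher by 4.47 ± 0.20, Itgax by 2.71 ± 0.20 and Il12b by 1.96 ± 0.12. Ankrd33b (-3.01 ± 0.08), Thbs1 (-2.88 ± 0.12), Tlr1 (-2.71 ± 0.16), Fos (-2.13 ± 0.13) and Vegfa (-1.41 ± 0.09) were lower. Interferon-stimulated genes were higher in 46 of 48 cases (48 adjusted over the list alone), with a median of 1.22 (0.74 without the IL10-/- arrays numbered 2) and a camera p of 2.36e-22 with the preset and 0.189 with the estimated correlation. Their list mean was higher without p50 by 1.30 (higher in 6 of 6 arrays than in both IL10-/- arrays at the same stimulus, exact permutation p 0.00926, the smallest possible with arrays taken as independent, adjusted 0.0185). Cholesterol synthesis genes were lower in 14 of 19 cases and higher in 0 (17 lower adjusted over the list alone, estimated-correlation p 0.163), and cell cycle genes in 18 of 31, such as Mcm7 (-0.98 ± 0.08, shared probes), also with 0 higher (estimated-correlation p 0.163). IL-10 and STAT3 response genes were lower in 11 of 22 cases, such as Ier3 (-1.19 ± 0.09), and higher in 4 (estimated-correlation p 0.163). Antimicrobial and lipid mediator enzymes were higher in 15 of 26 cases, such as Ptges (1.22 ± 0.10), and lower in 4, such as Lcn2 (-1.19 ± 0.08), with an estimated-correlation p of 0.163. Markers of neutrophils were lower in 10 of 12 cases, such as S100a9 (-1.09 ± 0.05), with an estimated-correlation p of 0.0255. Stromal markers were lower in 8 of 13 cases, such as Dcn (-1.62 ± 0.20) and Bgn (-1.47 ± 0.15), with an estimated-correlation p of 0.189. Their list mean read 7.04, 7.08 and 7.05 on the IL10-/- arrays numbered 2 (unstimulated, LPS, LPS with IL-10), against 6.69, 6.81 and 6.77 on those numbered 1, and these same arrays numbered 2 had the lower interferon-stimulated signal. Without them the median of stromal markers was -0.49 unstimulated, -0.50 with LPS and -0.34 with LPS and IL-10. On average it went from -0.63 to -0.51. This alternative was chosen after seeing the data and leaves 1 array in each IL10-/- group, so its calls of these markers are not counted. Macrophage identity genes were higher in 3 of 30 cases, such as Mertk (0.98 ± 0.11), and lower in 10, such as Ccr1 (-1.33 ± 0.18), with a median of -0.039 and a list mean lower by 0.138 (exact permutation p 0.0278, adjusted 0.0505). As a measure of RNA integrity and labelling, the difference between 3' and 5' control probes of the transferrin receptor was 2.02 log2 without p50 and 1.70 in IL10-/- cells (exact permutation p 0.00926, adjusted 0.0278), while those of Gapdh and actin differed by -0.14 (exact permutation p 0.102) and -0.07 (exact permutation p 0.315).

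**Figure D3:**
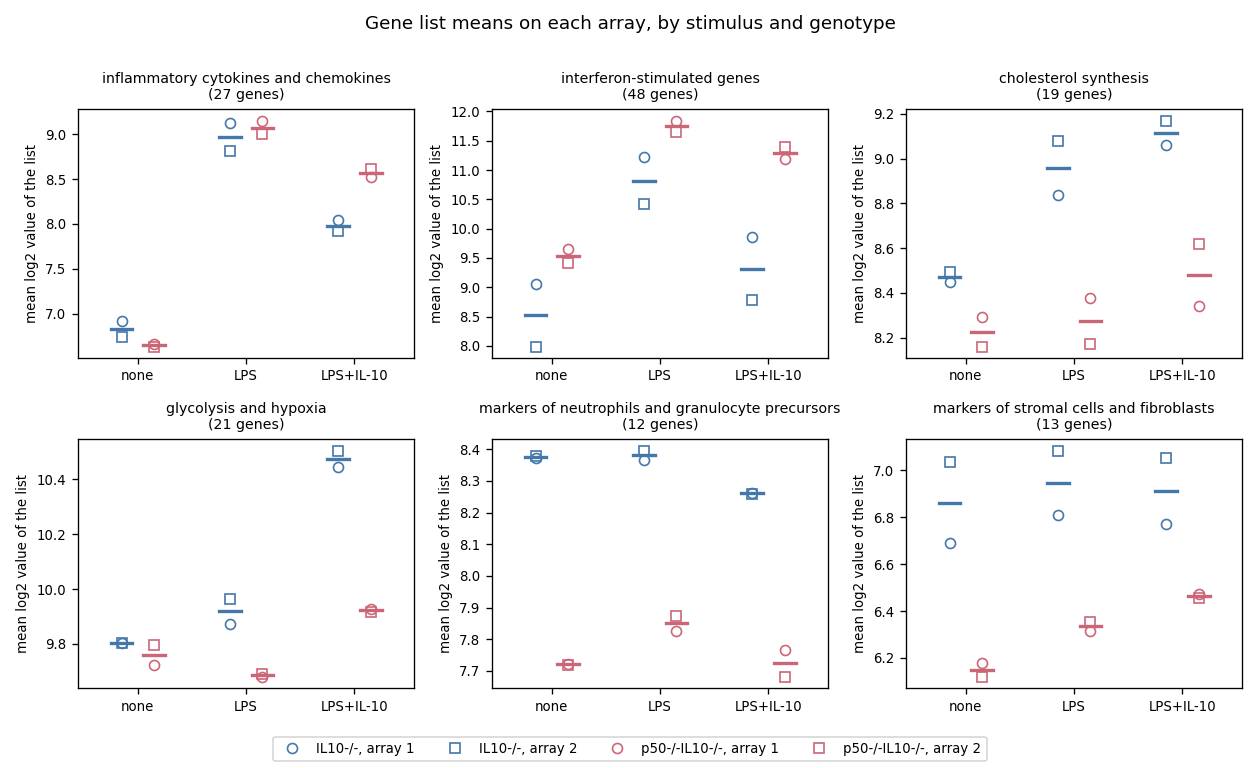
Mean log2 expression of 6 gene lists on each array (vertical axis) by stimulus and genotype (horizontal axis), with circles for arrays numbered 1, squares for arrays numbered 2 and bars at group means. Interferon-stimulated genes read 9.85 and 8.78 in IL10-/- cells given LPS and IL-10, against 11.18 and 11.39 in p50-/-IL10-/- cells, and neutrophil markers were lower without p50 on every array at its stimulus.

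Some genotype differences were called at every stimulus, which does not make them equal in size. At all 3 stimuli 92 genes were called higher and 91 lower without p50. Of the 156 genes higher in unstimulated cells, 112 were also higher with LPS (8.84 if independent), and of the 162 lower genes 111 were also lower (10.9 if independent). With LPS and with LPS plus IL-10, 442 higher genes (53.2 if independent) and 539 lower genes (86.8 if independent) were shared. Differences in unstimulated and LPS-treated cells correlated at 0.642 across genes, and those with LPS and with LPS plus IL-10 at 0.773. A difference called at every stimulus and at least 4-fold on average was found for 12 genes. Gbp2b, Gdpd3, Itgax, Qpct and Tmem87a were higher, and Ankrd33b, Ccn2, Clec4n (shared probes), Fos, Slfn8, Thbs1 and Tlr1 lower, a set defined after values were seen. For 3 of them the LPS response (Ankrd33b, Fos and Gbp2b) or the IL-10 effect (Ankrd33b) was also called different between the genotypes, for Gbp2b against a dim level in IL10-/- cells that leaves open how its difference changed. Of these 12, 2 had a second probe set, and both of those were called in the same direction. The calls of Fos and Slfn8 in unstimulated cells ended with 1 array left out (highest adjusted p 0.226, without p50-/-IL10-/- array 1, and 0.202, without p50-/-IL10-/- array 2).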

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

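The test of interferon signalling in single cultures, and the fit without the 3 IL10-/- arrays numbered 2, were chosen only after the results were seen. The position test was written before. The first set of results below was picked out because a direct test found the LPS response to differ between the genotypes, and the second because the IL-10 effect did.

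The LPS response differed between genotypes for 147 genes. The largest positive differences, meaning a higher change without p50, were in the lectin-like gene BC023105 (3.37 ± 0.49 log2, n = 2 arrays per group), Med21 (2.35 ± 0.23), the GTPase Gem (1.95 ± 0.33), Gbp2b (1.93 ± 0.30) and Nfil3 (1.87 ± 0.20). The largest negative ones were in Marco (-3.28 ± 0.44), Eno2 (-2.65 ± 0.25), Fos (-1.87 ± 0.32), the torsin family gene Tor4a (-1.79 ± 0.19) and Dusp1 (-1.77 ± 0.17). Of the groups compared, BC023105 and Gem in all but LPS-treated p50-/-IL10-/- cells, Eno2 in those cells and Gbp2b in IL10-/- cells read under 5.60 log2, the highest lower quartile of the arrays, so the sizes and ranks of these differences are uncertain. Leaving out 1 of the 8 arrays ended the call of Gem in 5 fits (highest adjusted p 0.0995, without unstimulated p50-/-IL10-/- array 1), of Fos in 4 (0.116, without LPS-treated p50-/-IL10-/- array 1), and of BC023105 and Gbp2b in 3 each (0.0639 and 0.0766, both without unstimulated p50-/-IL10-/- array 2). Med21, Nfil3, Marco, Eno2, Tor4a and Dusp1 stayed called in all 8. The median difference was 0.118 over inflammatory genes, -0.121 over phosphatases and mRNA decay factors, -0.431 over cholesterol synthesis genes, -0.237 over glycolysis and hypoxia genes and 0.160 over neutrophil markers. These 5 list calls rested on the preset correlation, since the estimated-correlation adjusted p was 0.278 for each. No explanation was tested for these genes beyond the genotype itself.

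The IL-10 effect differed between genotypes for 17 genes. Positive differences, a less negative or more positive effect without p50, were largest in Ptgs2 (2.08 ± 0.26 log2, n = 2 arrays per group), Il15 (1.92 ± 0.17), the early response gene Egr1 (1.82 ± 0.29), Tsc22d1 (1.61 ± 0.19, shared probes) and Ankrd33b (1.34 ± 0.20). Negative ones were largest in the metalloreductase Steap4 (-1.42 ± 0.17), Serpinb2 (-1.20 ± 0.11), the orphan receptor Gpr146 (-1.01 ± 0.10), Olfm1 (-1.003 ± 0.15) and the transcription factor Nfatc1 (-0.82 ± 0.10). Serpinb2 read under 5.60 log2 in 3 of its 4 groups here, and Ankrd33b in both p50-/-IL10-/- groups, so their sizes are uncertain. Il15, Serpinb2 and Gpr146 stayed called with each of the 8 arrays left out. The calls of Ankrd33b (all 8 fits) and Egr1 (7 fits) ended most often, with a highest adjusted p of 0.228 without array 2 of p50-/-IL10-/- cells given both, and that of Olfm1 ended in 7 (0.165, without LPS-treated p50-/-IL10-/- array 1). Those of Nfatc1 (6 fits), Ptgs2 (4), Steap4 (3) and Tsc22d1 (2) ended as well, with a highest adjusted p of 0.0845, 0.0845, 0.0824 and 0.0845 without array 1 of p50-/-IL10-/- cells given both. The median difference was 0.415 over inflammatory genes, 0.342 over NF-kB pathway genes, 0.978 over interferon-stimulated genes and -0.301 over glycolysis and hypoxia genes. With the estimated correlation the adjusted p-values of these lists were 0.162, 0.0542, 0.787 and 0.0802.

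Interferon-stimulated genes were higher without p50, in 46 of 48 cases averaged over the stimuli, with a camera p of 2.36e-22 with the preset but 0.189 with the estimated correlation. The labels give the same strain for both genotypes, and the strain in which Nfkb1 was targeted is not given in the sources used here. If that was another strain, passenger DNA carried along around Nfkb1 could change list members that lie near it. That alone is argued against as the whole source, because 46 of the 48 genes lie on other chromosomes and 44 of the 46 were called higher. The median shift of those was 1 times that of the list, which follows from their share of the list. Passenger DNA that acts on genes of other chromosomes was not tested and cannot be told apart from p50 loss here. A difference in interferon signalling between single cultures remains open and cannot be told apart from genotype here. If array numbers mark cultures, 2 against 2 allow no exact p below 0.333, whatever the values. The genotype difference of the list mean was 1.01 unstimulated, 0.926 with LPS and 1.97 with LPS and IL-10. The 2 IL10-/- arrays read 9.06 and 7.99, 11.22 and 10.42, and 9.85 and 8.78 at these stimuli. The smallest genotype difference was 0.861 times the largest replicate difference (1.07, in IL10-/- cells), a ratio that crosses stimuli. The 3 IL10-/- arrays numbered 2 read lower than their partners at every stimulus. Without them the median was 0.38 in unstimulated, 0.43 in LPS-treated and 1.46 in doubly treated cells, and 0.74 on average. In IL10-/- cells the fit without them gave medians of -1.36 with IL-10, 2.17 with LPS and 0.77 with LPS and IL-10 against no stimulus. It leaves 1 array in each IL10-/- group, so the spread among those arrays is lost and its calls of these genes are not counted here. A direct effect of p50 loss on these genes stays possible and was not tested apart from the genotype comparison.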

How the results depend on the processing

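The fit without the 3 IL10-/- arrays numbered 2 and camera with a block within genotypes were chosen after the data were seen. That fit leaves 1 array in each IL10-/- group, so its spread rests on the p50-/-IL10-/- arrays. No named gene reversed under any alternative. Of 585 called values of named genes, 26 were no longer called with the trended and robust prior, 17 with the mean of probe sets, 18 over all probe sets, 14 after quantile normalization again, 6 after centring and 2 with a replicate block over all groups, against 1 of 574 with the filter on dim genes, 65 of 527 in fits on only the groups compared, 62 of 415 without the 3 arrays numbered 2, and 462 of 2940 values over the fits with 1 array left out, where the lone array of a group is assumed to vary like the others. The block within genotypes ended 2 of 352 calls as a fixed term and 0 of 233 as a random one. The labels' replicate numbers share only a number between groups. Over 10 pairs of groups the replicate differences correlated at 0.17 to 0.59, and over the 5 pairs with p50-/-IL10-/- cells given LPS and IL-10 at -0.49 to -0.17. Numbers in that group may be crossed, which would change the counts with a block. Of 240 list results, the estimated correlation ended 59 calls, the dim filter ended 4 and added 2, and the block over all groups ended 2 and added 5. Of 160 between stimuli, the fixed block within genotypes added 8, and with the estimated correlation ended 26.

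Counts over all probe sets rose because more units were tested, to 4807 and 6363 for LPS, 3817 and 7191 for LPS with IL-10 against no stimulus (IL10-/- first), 532, 2360 and 5216 for p50 loss in unstimulated cells, in LPS-treated cells and on average, and 28 for the IL-10 effect difference. In fits on only the groups compared, counts were 1914 for LPS and 283 for IL-10 in IL10-/- cells, 581 for p50 loss with LPS, and 78 and 10 for the LPS and IL-10 effect differences, while in p50-/-IL10-/- cells they were 4032 for LPS and 5089 for LPS with IL-10 against no stimulus. Without the 3 arrays numbered 2 they were 1512 for LPS with IL-10 against no stimulus in IL10-/- cells, 204, 940 and 1407 for p50 loss in unstimulated, LPS-treated and doubly treated cells, and 74 and 30 for the LPS and IL-10 effect differences. The IL-10 effect difference became 26 with the mean of probe sets and 74 with the fixed block within genotypes, of which 17 were shared with the first count. Except for the tests over all probe sets, the cause was not tested. IL-10 lowered 26.5% of LPS-raised genes of IL10-/- cells with no fold threshold, which admits smaller responses, and 13.4% in p50-/-IL10-/- cells for genes from the other genotype.

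Leaving out 1 array gave ranges of 1950 to 3551 and 2790 to 3325 for LPS, 426 to 1082 and 270 to 479 for IL-10, and 1469 to 1910 and 2909 to 3330 for LPS with IL-10 against no stimulus (IL10-/- first). For p50 loss they were 101 to 244, 671 to 1896 and 987 to 1504 by stimulus and 2560 to 3557 on average. For the LPS and IL-10 effect differences they were 32 to 255 and 4 to 43. Dim genes lie near the array floor of 3.21 to 3.29 log2, where changes are compressed.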

Other observations

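The tests on cell type markers, on differences called at every stimulus, on 2-fold differences near Nfkb1 and on splits by array number were chosen only after those results were seen. The tests of splits of single arrays and of the share of called genes near Nfkb1, and the comparison with other probe sets, were planned before.

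IL-10 raised the phospholipase Pla2g4a by 1.66 ± 0.11 log2 in IL10-/- and 1.78 ± 0.11 in p50-/-IL10-/- cells (n = 2 arrays per group). The prostaglandin synthase Ptges was higher without p50 by 1.20 ± 0.18 with LPS and by 2.03 ± 0.18 with LPS and IL-10. The heat shock gene Hspa1b rose with LPS by 1.74 ± 0.25 in IL10-/- and 2.19 ± 0.25 in p50-/-IL10-/- cells, and IL-10 changed it by -1.31 ± 0.25 and -1.56 ± 0.25. Hspa1a rose with LPS by 0.56 ± 0.16 in IL10-/- and 1.40 ± 0.16 in p50-/-IL10-/- cells, where IL-10 changed it by -1.40 ± 0.16. Neither gene was called for a genotype difference of the LPS response or the IL-10 effect, and Hsph1 of the same list fell with LPS in both genotypes (-0.92 ± 0.18 and -1.31 ± 0.18). The efferocytosis receptor Mertk fell with LPS in IL10-/- cells, fell again with IL-10 (-1.27 ± 0.19), and was higher without p50 by 1.29 ± 0.19 with LPS and 1.62 ± 0.19 with LPS and IL-10.

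The MHC class II transactivator Ciita was higher without p50 by 0.90 ± 0.13 log2 with LPS and by 0.98 ± 0.13 with LPS and IL-10 (n = 2 arrays per group), while averaged over the stimuli 1 of the 10 class II presentation genes was higher and 1 lower. Heat shock and immediate early genes split on average into 5 higher, such as Hspa1a (0.83 ± 0.09), and 5 lower, such as Fos (-2.13 ± 0.13), of 18. Of 11 dendritic cell markers 1 was higher on average, the integrin Itgax, and 3 with LPS and IL-10 (also Flt3 and Zbtb46, the latter dim in both groups). Their list mean was higher on average by 0.242 (exact permutation p 0.00926 with arrays taken as independent, adjusted 0.0185), with a median of 0.020 and an estimated-correlation p of 0.441. Itgax (2.71 ± 0.20 on average) accounts for this list mean, so the permutation test shows little beyond that 1 gene. Of 11 B cell and 12 T and NK cell markers 0 were called on average, and 2 of each had an unadjusted p under 0.05 in limma. Of 8 erythroid markers 1 was higher (Car2, 0.26 ± 0.06) and of 10 mast cell and basophil markers 1 was lower (Mcpt8, -0.22 ± 0.05). With LPS and IL-10, list means without p50 were higher by 0.107 for B cell and 0.0856 for T and NK cell markers. Those of erythroid and mast cell markers were higher by 0.184 and 0.0599. The p50-/-IL10-/- arrays given both also had the highest lower quartiles (5.60). The calls of Flt3 and Zbtb46 there cannot be told apart from a rise shared with markers of other cell types. Co-stimulation and adhesion genes were higher in 6 of 17 cases, such as Cd40 (0.93 ± 0.09), with an estimated-correlation p of 0.163, and lower in 2, Cd86 (-1.02 ± 0.10) and Cd83 (-0.56 ± 0.09).

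On average 8 of 13 stromal markers and 10 of 12 markers of neutrophils and their precursors were called lower without p50. The stromal list had a camera p of 0.000129 with the preset but 0.189 with the estimated correlation, the other list 0.0255 with the latter. All 7 of 7 stromal markers that read at least 7 log2 in unstimulated IL10-/- cells fell on average (-0.53 to -1.62), as did 7 of 7 such granulocyte markers (-0.31 to -1.21), which restates the pattern and does not explain it. Fewer cells of a type would lower markers that only it expresses by the same amount, apart from compression of dim signals. The largest and smallest falls lay 1.09 log2 apart for stromal and 0.904 for granulocyte markers. The 95% error of 1 pair fixed beforehand is 0.420 and 0.227, but these pairs were the extremes of 7 markers. The gaps therefore cannot decide this. Macrophages can express part of these markers themselves, so fewer stromal cells or fewer granulocytes cannot be told apart from lower expression per cell without p50. The macrophage identity genes went both ways, with 3 higher and 10 lower, a median of -0.039 and a list mean lower by 0.138 (exact permutation p 0.0278, adjusted 0.0505), so a weaker macrophage signal overall stays open too. The labels name no sorting of the cells.

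Genotype differences called at every stimulus and at least 4-fold on average were weighed against passenger DNA and sequence variants. Called genes were not concentrated near Nfkb1, since 36 of 135 genes within 20 Mb and 3139 of 12234 others were called (ratio of shares 1.04), and 11 of these 12 genes lay outside that window. DNA differences between the mouse lines elsewhere in the genome were not tested. Among 2-fold differences, 6 of the 135 genes (Extl2, Gbp2b, Gbp3, Gbp7, Ifi44l and Mcoln3, picked after their values were seen) against 168 of 12234 gave a ratio of 3.24 (Fisher's exact test, two-sided, p 0.012). This test takes genes as independent, but Gbp2b, Gbp3 and Gbp7 belong to 1 family, and interferon-stimulated genes were higher together. The p therefore cannot decide on an excess near Nfkb1. Passenger DNA may contribute there, and genotype itself stays open for the interferon-inducible ones among them. For Gbp2b, the 1 of these 12 genes in the window, passenger DNA and p50 loss cannot be told apart (Fisher's exact p 0.123). A variant under 1 probe set is argued against for Clec4n and Thbs1, whose second probe sets changed by a median of 0.89 times as much, and stays open for the other 10 genes, which have a single probe set.

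Chance can be excluded as the source of the averaged p50 effect only if the 12 arrays are independent samples. Of 100 splits of the arrays into groups of the same size within stimuli, 1, the real one, then called as many as 3182 genes, and the highest other count was 1595. The next ones, 1448, 1446 and 1405, also kept both stimulated pairs of groups apart, as did the highest, and the one after these called 110. Replicate differences correlated at 0.398, 0.595 and 0.586 among the IL10-/- groups, so arrays of 1 number may stem from 1 culture. Leaving out p50-/-IL10-/- cells given both, they also correlated at 0.169 to 0.298 between genotypes. A shared culture cannot give that, so numbers may mark something else as well. With arrays of 1 number in a genotype moved together there are 3 splits, too few for a share under 0.333, where 1, the real one, called 3182 genes and the highest other 0. Numbers of p50-/-IL10-/- cells given LPS and IL-10 may be crossed, which would change the other splits.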
